A study of Mus musculus with 2 samples.

How the data were processed

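RNA was sequenced from cardiac ventricles of 16-week-old C57BL/6 mice of 2 genotypes. The labels name 2 samples, 1 per group. The Flox sample carried the Tbx5LDN/LDN allele alone, and the vTBX5KO sample carried it together with Myh6-MerCreMer, a cardiomyocyte transgene for a Cre recombinase that is switched on by an oestrogen receptor ligand. Per the labels' protocols, mice received TX at 30 mg/kg per day for 3 days at 12 weeks of age and were killed 4 weeks later, and the protocol text is the same for both samples. Libraries were made from total RNA with an Illumina protocol, and whether the kit kept strand is not given in the sources used here.

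The only values analysed were those of 1 table of a comparison named group B against group A. Per the submitters' processing notes, the genome build was mm9 and the tools included Bowtie2 2.0 and DESeq2, with no role or order given. How reads were counted per gene is not given in the sources used here. Per the file headers, the table holds for each gene a mean normalized count over all libraries, a log2 fold change and an adjusted p-value. The deposited mean normalized count is a signal pooled over both groups, that is, reads divided by a size factor per library. The deposited log2 fold change is shrunken towards 0, since genes with a single read had values under 0.1 in size. The authors' adjusted p-value was taken as deposited. Gene names and coordinates were taken from the table. Of 36602 gene identifiers that matched GENCODE M21, 25481 (69.6%) had the identical chromosome, start and end in that annotation of build GRCm38. The coordinates are therefore given as GRCm38, although the notes name mm9.

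No label, header or note used here says which genotype is group A and which is group B. The genotype was not inferred from the values. Every direction is given as group B relative to group A, and the comparison of vTBX5KO with Flox has that direction left open.

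The table lists 38355 genes. Of these, 14885 had no reads and 13230 had an adjusted p-value. The lowest mean among the latter was 16.0, and 194 genes above that mean had no adjusted p. A gene was called at an adjusted p under 0.05. The table holds no standard error and no unadjusted p-value. The Benjamini-Hochberg adjustment was inverted over the 13230 genes to give the largest p each adjusted p allows, and the log2 fold change was divided by the matching normal quantile to give a standard error, which is an upper bound for the 10627 genes that share an adjusted p with another gene. The inversion was tested on simulated data. With these bounds the median standard error was 0.20 on the log2 scale.

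Reads per library were recovered from the pooled means. Genes with a single read in 1 library share the same mean, and 6 such step values were found, each shared by at least 100 genes. The sign of the fold change of those genes gave the letter of the library, 3 of group A and 3 of group B. The whole reads of a gene were then the set of 6 whole numbers whose sum of steps equals the deposited mean to 15 digits. For means under 100, 13377 of 13403 genes (99.8%) had exactly 1 such set, and the recovered reads differed from the mean by a relative difference of at most 4.92e-15. With steps shifted by a few 1e-06 of their size, 0% of 2378 genes with a mean from 5 to 20 had a set. On 12264 simulated genes, 97.8% were solved and 100% of the solved genes had the right reads. Libraries are named by letter and numbered from the deepest to the shallowest within a letter. Their size factors were 1.16, 0.80 and 0.61 for A1, A2 and A3, and 1.56, 1.35 and 0.89 for B1, B2 and B3. Total reads per library were not recovered. Nothing in the labels says whether the 3 libraries of a letter came from separate animals, so p-values measure the spread between these libraries, which may be technical.

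The fold changes and adjusted p-values of the authors' deposited table are the main result. The planned count test on libraries mapped to genotype was not used, because the file holds no count column and no mapping. Gene lists were written before the data were examined, 18 of them for pathways and gene classes and 13 of cell type markers, with 650 members in all. For each list the members with calls were counted in each direction and compared with all other tested genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 60 tests. Fisher's test treats genes as independent, and its background was not matched on expression. The median log2 fold change of each list was ranked among 10000 random lists of the same size matched on deciles of the mean, as a description. A count adjusted over the list alone used the recovered p-value bounds and was not corrected for the number of lists. Named genes were, by a rule also written before, Tbx5, the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean of at least 50 and no overlap of recovered libraries, and up to 4 members per list with the smallest adjusted p. Genes outside this rule were chosen after their values were seen: Rsad2, Ifi44, Ifit3, Ccl8 and Npas2, which complete the calls of a list, and Dbh, Nppa, Egr2, Egr3, Fosb, Ucp1, Adipoq, Bmp10 and Xist. Patterns in the closing section were also found after the values were seen. Some genes that the rule takes are not reported here.

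Alternatives planned before the data were examined were adjusted p thresholds of 0.01 and 0.1, a minimum mean of 10 for genes, list members and the background, a minimum absolute log2 fold change of 1, log2 ratios of the group values with pseudocounts of 1 and 10, and rescaling to a median log2 ratio of 0 for genes with a mean of at least 100. Added after seeing the data was a limma-voom refit of the recovered reads of 3324 tested genes, with all 6 libraries and without each in turn. Ratios of recovered group means without each library in turn were also added after seeing the data. In simulated reads of those 3324 genes, 1 dispersion of 0.03 was set for all genes and 200 genes were changed. There the refit called 68% of genes changed 2-fold and 100% of genes changed 4-fold, with 5 calls among the unchanged genes. The dispersion of the real reads was not estimated. Near-identical transcripts were sought with blastn 2.17.0 in the GENCODE M21 transcripts with at least 95% identity over most of the shorter sequence. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.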

Results

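The study profiled gene expression in the cardiac ventricles of adult mice, to ask what the loss of the T-box transcription factor Tbx5 from ventricular cardiomyocytes does to the ventricular transcriptome. The labels name 1 Flox and 1 vTBX5KO sample, and the pooled means of the authors' deposited table resolved into 6 libraries, 3 of group A and 3 of group B. The deepest library had 2.58 times the size factor of the shallowest. The size factors ran from 0.61 in A3 to 1.56 in B1, and total reads per library are not given in the sources used here. The 10 highest genes held 18.9% of the summed mean normalized counts in the authors' deposited table. Which letter is the knockout is open, so each value below compares group B with group A.

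Tbx5 itself (ENSMUSG00000018263, chromosome 5, 119834663 to 119885218 on GRCm38) was read in these ventricles at a mean normalized count of 513 in the authors' deposited table. Its log2 fold change there was 0.92, that is, 1.89-fold higher in group B, with a standard error of at most 0.30. The adjusted p of 0.0575 in the authors' deposited table missed the threshold of 0.05. The value covers the whole gene, and the part of the transcript that the allele deletes is not given in the labels, so this value does not check which letter is the knockout.

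Between the groups, calls lower in group B were more frequent among genes of the ion channel and conduction list, of the immediate early response and of the fetal and hypertrophy programme, and calls higher in group B among interferon genes. The immediate early and fetal lists lost this with calls at an adjusted p under 0.01 (adjusted Fisher p = 0.389 for each). These tests did not match genes on expression. Among protein-coding genes, 6 of 1207 in the tenth with the lowest means were called lower, against 84 of 1207 in the tenth with the highest. How far this raised the share of lower calls in the lists was not tested. Of 13230 genes with an adjusted p in the authors' deposited table, 527 were called, 198 higher and 329 lower in group B. The lower genes had the higher expression, with a median mean of 807 normalized counts against 141 for the higher genes in the authors' deposited table. Most changes were below 2-fold, and 109 calls had an absolute log2 fold change of at least 1, of which 49 were higher and 60 lower. At an adjusted p under 0.01 the authors' deposited table gave 294 calls, 97 higher and 197 lower. The plot of fold change against mean count shows these calls. In protein-coding genes the median log2 fold change went from -0.09 in the tenth with the shortest genomic span to 0.11 in the tenth with the longest, over all genes in the authors' deposited table with an adjusted p.

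**Figure D1:**
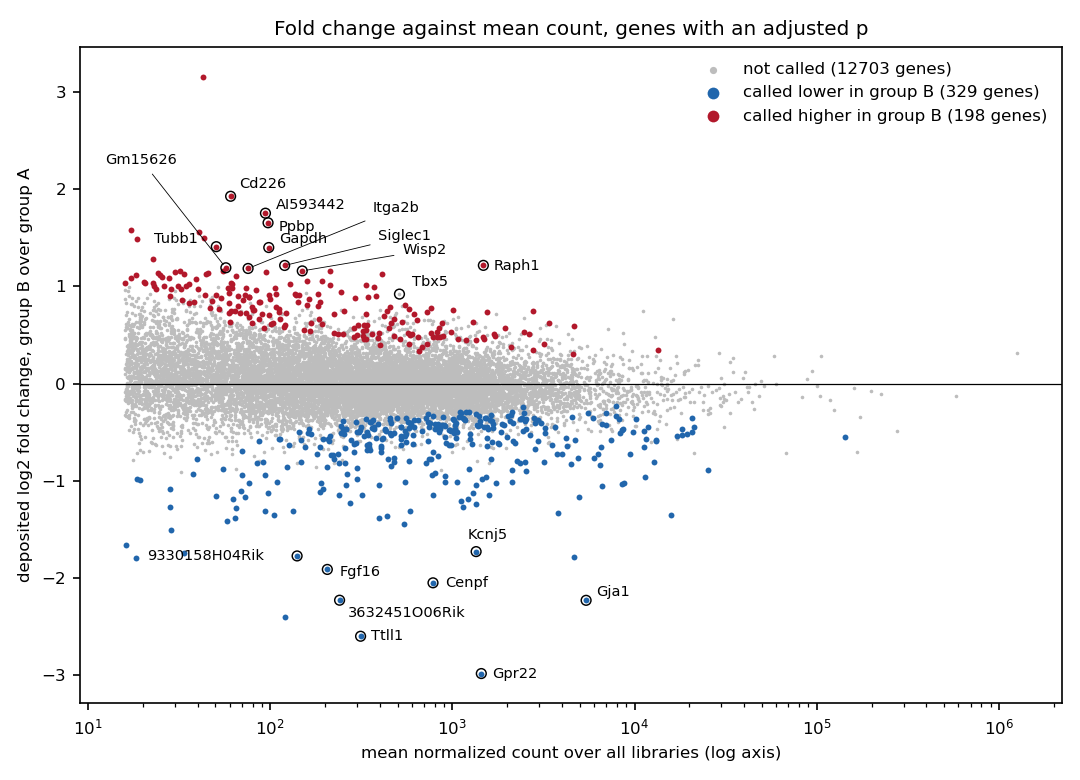
Deposited log2 fold change of group B over group A (y axis) against the mean normalized count over all libraries (x axis, log scale) for the genes with an adjusted p. Each point is a gene, red for the 198 called higher in group B, blue for the 329 called lower and grey for the rest, and circled points carry the names of Tbx5 and of genes among the largest rises and falls of called genes with a mean of at least 50, from 1.93 for Cd226 to -2.98 for Gpr22.

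Among called genes with a mean of at least 50, the largest falls were in genes of cell coupling and membrane excitability together with genes of other functions. Gpr22, an orphan receptor of heart and brain, was 7.91-fold lower in group B in the authors' deposited table, with a log2 fold change of -2.98, a standard error of at most 0.24 and an adjusted p of 6.57e-33. Gja1, which encodes the gap junction protein connexin 43, was 4.69-fold lower at a mean of 5423 normalized counts (log2 fold change -2.23, standard error at most 0.19, adjusted p 1.60e-29 in the authors' deposited table). Kcnj5, a subunit of the acetylcholine-gated potassium channel, was 3.31-fold lower in the authors' deposited table. Further falls of the authors' deposited table were Ttll1 at -2.60, 3632451O06Rik at -2.23, Cenpf, a centromere protein, at -2.05, Fgf16, a fibroblast growth factor, at -1.91 and 9330158H04Rik at -1.77 on the log2 scale.

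The genes called higher had fewer reads. Among called genes with a mean of at least 50 the largest in the authors' deposited table was Cd226, an adhesion receptor of platelets and lymphocytes, at a log2 fold change of 1.93 with a standard error of at most 0.31 and an adjusted p of 1.17e-07, and its recovered reads were 15.3 ± 11.1 in group A and 106 ± 31.1 in group B (SD, n = 3 libraries). The ratio of these group means was 6.94, and 11.9 without A3. It was followed in the authors' deposited table by AI593442 at 1.75, Ppbp, a platelet chemokine, at 1.65 and Tubb1, the platelet beta tubulin, at 1.41. Itga2b, the platelet integrin alpha chain, stood at 1.18, Siglec1, a sialic acid receptor of macrophages, at 1.21, Raph1 at 1.22, Gm15626 at 1.19 and Wisp2 at 1.16 in the authors' deposited table. The deposited fold changes are shrunken, and the ratios of the recovered group means were 5.55 for Tubb1 and 4.28 for Itga2b. Without B1 they were 3.50 and 2.43, and without A3 the ratio of Tubb1 was 8.56. Gapdh, the glycolytic enzyme, was 2.64-fold higher in the authors' deposited table with a mean of only 98.2 normalized counts. Its transcript has 75 near-identical genes in the annotation, and how reads that fit several genes were counted is not given in the sources used here, so its value is uncertain.

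For genes with a mean under 100 the values per library behind the calls were recovered. All 108 called genes in that range had no overlap between the 3 libraries of each group, which the calls themselves largely fix since they rest on the same reads. Of 3216 genes that were not called, 16.5% had no overlap. For a single gene the chance of this is 10%. Genes read in the same libraries are not independent, and the share was not computed for other splits, so no excess over chance is read from it. The limma-voom refit of these reads, chosen after seeing the data, called 19 genes at an adjusted p under 0.05, 7 higher and 12 lower in group B, and all 19 were among the 108. Without library B3 it called 145 genes (116 higher, 29 lower), without B1 42 (21 higher, 21 lower) and without A3 14 (5 higher, 9 lower). Without B2 it called 3 genes and without A1 or A2 1 gene each, all higher in group B.

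Genes for ion channels and conduction stood out among the lists. Of 35 tested members, 7 were lower in group B, none higher and 28 not called in the authors' deposited table (Fisher's exact test, adjusted p = 6.11e-04). Besides Kcnj5, the lower members of the authors' deposited table included Kcnip2, a subunit of the transient outward potassium current, at -0.80, Cacnb2, a calcium channel subunit, at -0.64, and Cacna1g, a T-type calcium channel, at -1.15. Adjusted over the list alone, 7 members passed, and the median of -0.26 lay at percentile 0 of the random lists. Of 17 tested gap junction and intercalated disc genes, Gja1 alone was called in the authors' deposited table, and 2 passed when adjusted over the list alone, Gja1 and Gja3 (-0.47). The values of Dsc2 (0.27) and Cdh2 (-0.32) passed neither. The conduction system markers had 1 call among 9 tested members, Cacna1g, with 4 adjusted over the list alone and a median of -0.51 at percentile 0. Their uncalled members Gja5, Irx3 and Etv1 stood at -0.56, -0.54 and 0.56 in the authors' deposited table. Of 10 tested atrial markers only Chrm2, the muscarinic receptor, was called, at -1.33 in the authors' deposited table. Adjusted over the list alone, 4 of the atrial markers passed. They were Chrm2, Stard10 (-0.64) and Fam189a2 (-0.28), all lower, and the targeted gene Tbx5, which is in this list and was higher (0.92).

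Calcium handling genes had 1 call among 18 tested, the calsequestrin Casq1 at -0.80 in the authors' deposited table, but 6 passed when adjusted over the list alone and the median of -0.23 lay at percentile 0.07. The values of Ryr2 (-0.71, adjusted p 0.0671) and Jph2 (-0.49, adjusted p 0.0528) in the authors' deposited table missed the threshold over all genes and passed over the list alone. No cardiac transcription factor of 24 tested was called in the authors' deposited table, and none passed when adjusted over the list alone. The nearest were Srf at -0.45 with an adjusted p of 0.0670, Irx3 at -0.54, Irx5 at -0.66 and Hopx at -0.48 in the authors' deposited table.

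Of 17 tested genes of the fetal and hypertrophy programme, 4 were lower and 1 higher in group B in the authors' deposited table (adjusted p = 0.0104 for the lower calls). Nppb, the B-type natriuretic peptide, was 2.21-fold lower and Ctgf, a matricellular growth factor, 1.97-fold lower, with Actc1 at -0.55 and Uchl1 at -0.59, while Fhl1, a LIM protein, was 1.67-fold higher in the authors' deposited table. At calls under 0.01 this list kept 2 lower members and its adjusted p was 0.389. Adjusted over the list alone, 7 members passed. Nppa, the atrial natriuretic peptide, had no adjusted p in the authors' deposited table and a log2 fold change of -0.47. The sarcomere list had 2 lower genes among 20 tested, Lmod2 at -0.72 and Cryab at -0.80 in the authors' deposited table, with 3 adjusted over the list alone. Myl2 (-0.70) was the member that passed over the list alone only, and the value of Tcap (-0.25) in the authors' deposited table passed neither.

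Immediate early genes were lower in group B in 4 of 16 tested members and higher in none in the authors' deposited table (adjusted p = 0.0104). Junb was 2.57-fold lower, Cyr61 2.35-fold, Ier2 2.03-fold and Ier3 1.63-fold in the authors' deposited table. The median of -0.59 lay at percentile 0, and 6 passed when adjusted over the list alone. At calls under 0.01 the list kept 2 lower members and its adjusted p was 0.389. The recovered reads of Egr2, Egr3 and Fosb, named after their values were seen, did not fall evenly on the libraries of group A. Egr2 was at 155 and 147 normalized reads in A1 and A2, 11.5 in A3, and 6.39 to 8.13 in group B. Fosb was at 41.5 and 17.6 in A1 and A2 and 3.29 in A3, and Egr3 at 21.6, 22.6 and 1.65. The 4 called members had means from 190 for Ier2 to 1352 for Cyr61, so their reads per library were not recovered. Whether their lower calls rest on A1 and A2 is therefore open.

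Interferon response genes were higher in group B in 7 of 21 tested members and lower in none in the authors' deposited table (adjusted p = 8.84e-07). Mx2 was 2.15-fold higher, Ifit1 1.90-fold, Irf7 1.79-fold and Ifit2 1.75-fold in the authors' deposited table, and Rsad2, Ifi44 and Ifit3 were called at 0.57, 0.69 and 0.74. Adjusted over the list alone, 15 members passed, and the median of 0.57 lay at percentile 100. The recovered reads of Mx2 were 37.0 ± 9.58 in group A and 93.0 ± 12.3 in group B (SD, n = 3 libraries). Of 23 tested inflammation genes, Ccl8 alone was called, at 0.98 in the authors' deposited table, with 2 adjusted over the list alone. Cxcl14 (-0.49) passed over the list alone only, and the values of Cxcl9 (0.62), Ptgs2 (-0.50) and Cx3cl1 (-0.49) passed neither in the authors' deposited table. The plot of list members shows how these lists lie to each side of 0.

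**Figure D2:**
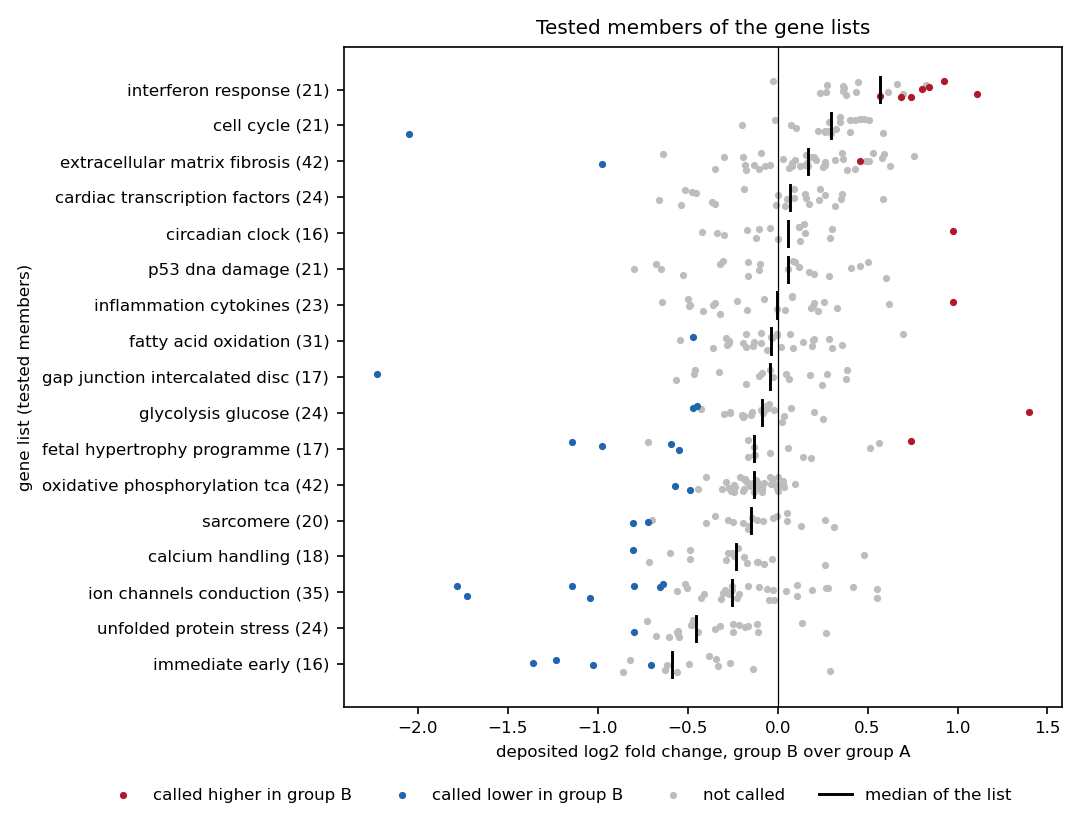
Deposited log2 fold change of group B over group A (x axis) of the tested members of 17 gene lists (y axis, number of tested members in brackets). Each point is a gene, red if called higher in group B, blue if called lower and grey if not called, and the black bar is the list median, from -0.59 for immediate early genes to 0.57 for interferon genes.

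Metabolic and stress lists had few calls. Among 42 tested genes of oxidative phosphorylation and the citrate cycle, Cox6a2 (-0.57) and Idh3a (-0.49) were lower in the authors' deposited table, with 2 adjusted over the list alone and a median of -0.13 at percentile 2.12. Etfb (-0.47) was the single call among 31 fatty acid oxidation genes in the authors' deposited table, with 1 adjusted over the list alone. Of 24 tested glycolysis genes, the muscle phosphofructokinase Pfkm (-0.47) and the lactate dehydrogenase Ldhb (-0.45) were lower and Gapdh higher in the authors' deposited table, with 4 adjusted over the list alone. The heat shock protein Hspb1 (-0.80) was the single call among 24 genes of the unfolded protein and stress response in the authors' deposited table, with 1 adjusted over the list alone, while the list median of -0.45 lay at percentile 0. No p53 and DNA damage gene of 21 tested was called in the authors' deposited table, and 6 passed when adjusted over the list alone. These went both ways. Rrm2b (-0.32), Gadd45b (-0.53), Gadd45g (-0.65) and Btg2 (-0.80) were lower, and Eda2r (0.60) and Trp53inp1 (0.50) were higher. The list median was 0.06. Of 21 tested cell cycle genes only Cenpf was called, lower in group B in the authors' deposited table, with 1 adjusted over the list alone, against a list median of 0.30 at percentile 99.96. The clock gene Npas2 (0.98) was the single call among 16 in the authors' deposited table, with 2 adjusted over the list alone. The 4 tested Y-linked genes were read in the authors' deposited table, with Ddx3y at a mean of 3724 normalized counts, and none was called. Xist, chosen for this after its value was seen, had a mean of 3.79 in the authors' deposited table.

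Extracellular matrix genes had 1 higher and 1 lower call among 42 tested, Mfap5 at 0.46 and Ctgf at -0.98 in the authors' deposited table, with 6 adjusted over the list alone and a median of 0.17 at percentile 100. Col5a2 (0.36, adjusted p 0.0540) and Fstl1 (0.51, adjusted p 0.0671) passed over the list alone but not over all genes in the authors' deposited table. At calls under 0.1, 5 members of this list were higher with an adjusted Fisher p of 0.0329.

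No cell type list passed Fisher's test after adjustment. Of 18 tested macrophage markers, Mrc1 (0.46) and F13a1 (0.51) were higher in the authors' deposited table, with an adjusted p of 0.291, 2 adjusted over the list alone and a median of 0.25 at percentile 99.98. The fibroblast markers had Mfap5 as the single call of 15 tested in the authors' deposited table, 1 adjusted over the list alone and a median of 0.22 at percentile 99.99. Nerve and Schwann cell markers had 2 lower calls among 8 tested in the authors' deposited table, the ubiquitin hydrolase Uchl1 and, outside the rule for named genes, the noradrenaline enzyme Dbh at -1.79, with 3 adjusted over the list alone and an adjusted Fisher p of 0.188. Dbh had 31.6 ± 2.17 recovered reads in group A and 4.91 ± 2.40 in group B (SD, n = 3 libraries), and its log2 fold change in the limma-voom refit was -2.65 with a standard error of 0.44 and an adjusted p of 0.0162, a call that was lost without A1, without A2 and without B2. Red cell genes had no call among 7 tested in the authors' deposited table, none adjusted over the list alone, and a median of 0.48 at percentile 99.99. The smooth muscle and pericyte list held 1 call among 13 tested, Abcc9, in the authors' deposited table, with 1 adjusted over the list alone and a median of 0.14. Ventricular cardiomyocyte markers had no call among 13 tested in the authors' deposited table, with 1 adjusted over the list alone and a median of -0.03. Endothelial markers had no call among 16 tested, neutrophil markers none among 3, adipocyte markers none among 8 and mesothelial markers none among 9 in the authors' deposited table, none of them adjusted over the list alone. Their medians were -0.04, -0.00, 0.14 and 0.16. No lymphocyte marker had an adjusted p in the authors' deposited table.

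Single libraries differed in tissue markers within both groups. Ucp1, the uncoupling protein of brown fat, was at 52.7 normalized reads in A3 and 118 in B3 and at 1.73 to 3.77 in the other libraries. Adipoq, a fat cell hormone, was at 105 in A3 and 109 in B3. Msln, a mesothelial surface protein, was at 6.06 in A1 and at 52.8 to 147 in the other libraries. Bmp10, an atrial growth factor, was at 72.5 in A3 and 0 in A1 and A2. Ucp1, Adipoq and Bmp10 were named after their values were seen. The plot of reads per library sets some of these beside genes that separate the groups.

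**Figure D3:**
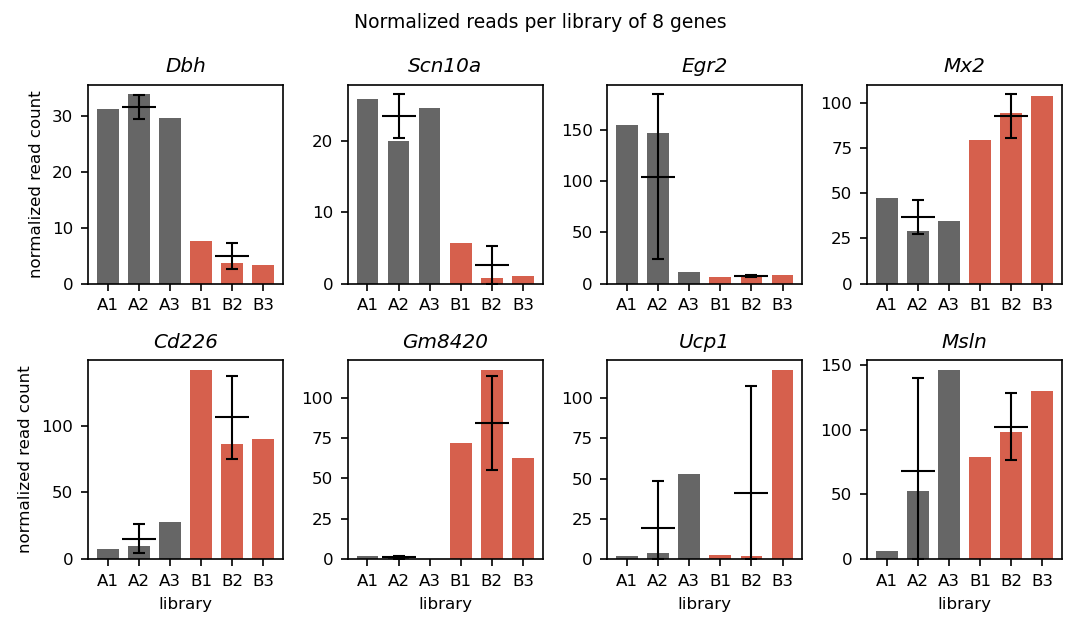
Recovered normalized read count (y axis, from 0, a scale of its own in each panel) of 8 genes in the 6 libraries (x axis), grey for group A and red for group B. The horizontal mark and bar give the mean and SD of the 3 libraries of a group, the bar being drawn no lower than 0, and Dbh for example has 31.6 ± 2.17 in group A and 4.91 ± 2.40 in group B.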

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

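The search behind this part, its bounds of 50 reads and 4-fold, and the folds without a library were chosen only after the data were seen. It covered genes that have no adjusted p in the authors' deposited table and whose reads per library were recovered. Genes with the lowest means were left out of it, whatever their number of reads. Of 1173 such genes with at least 50 reads, 223 (19.0%) had no overlap between the 3 libraries of each group. The chance for a single gene is 10%, but the genes share the same libraries, so no excess over chance is read from this. Of the 223 genes, 15 differed at least 4-fold between the means of the groups, 6 higher in group A and 9 higher in group B. These differences carry no test of their own.

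Among the 6 genes higher in group A, Egr2, an immediate early transcription factor, had the largest fold of 14, and it was high in A1 and A2 and at 11.5 normalized reads in A3. Scn10a, a sodium channel gene of sensory neurons, was 9.29-fold higher in group A, with 23.6 ± 3.08 normalized reads there and 2.54 ± 2.79 in group B (SD, n = 3 libraries), and without B1 the fold was 25.3. Zcchc5 was 5.14-fold higher in group A, Tnni2, the fast skeletal troponin I, 4.51-fold, Gm4524 4.45-fold and A1cf 4.35-fold.

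Among the 9 genes higher in group B, Gm14094 had the largest fold of 54.7, from 1 read in group A and 90 in group B. Its ratio of reads per summed size factor was 60.5 with an exact 95% interval from 10.6 to 2414, which covers counting error only and not the spread between libraries, and without A2 group A had no reads. Gp5 and P2rx1, a platelet glycoprotein and a platelet ATP receptor, were 7.24-fold and 5.55-fold higher in group B, and the fold of Gp5 was 4.21 without B1. Gm15859 was 5.79-fold, 6430550D23Rik 5.07-fold, Gm24041 4.75-fold, Gm6634 4.34-fold, Mir30a 4.19-fold and Gm14209 4.12-fold higher in group B. Leaving out 1 library took 7 of the 15 genes below the bound of 4. Their lowest folds were 2.50 for Gm6634, 3.28 for Gm14209 and 3.85 for Gm4524, each without B1, 3.47 for Mir30a and 3.48 for A1cf, each without A1, 3.56 for Gm24041 without A2 and 3.38 for 6430550D23Rik without A3. The fold of Gm15859 was 8.81 without A3, and without A2 that of Mir30a was 6.37 and that of 6430550D23Rik 8.29.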

How the results depend on the processing

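The limma-voom refit and all runs without a library were chosen only after the data were seen. The count of 527 called genes became 294 at an adjusted p under 0.01 (97 higher, 197 lower in group B), 782 under 0.1 (307 higher, 475 lower) and 109 with an absolute log2 fold change of at least 1 (49 higher, 60 lower), by construction of the thresholds. Tbx5 passed at 0.1 with its adjusted p of 0.0575, and its log2 value ran from 0.90 to 0.94 over the pseudocounts and the rescaling. Genes without recovered reads, Tbx5 among them, had group values derived from the deposited mean and fold change, so this range tests nothing. The number of lists that passed went from 4 to 2 with calls under 0.01, where the fetal and immediate early lists had an adjusted p of 0.389, and to 6 with calls under 0.1, where 4 calcium handling genes (adjusted p 0.0336) and 5 matrix genes (0.0329) were added. No cell type list passed under any of these settings. Of 252 pseudocount values of named genes 13 moved by more than the standard error, in 9 genes, and 0 reversed. A pseudocount added to both group values cannot turn the sign of their ratio, so the 0 is no test of the pseudocounts. The largest moves were those of Tubb1 to 2.40 and Itga2b to 2.06 on the log2 scale with a pseudocount of 1. For both genes, recovered group means replaced the shrunken fold change. Rescaling by -0.02 is too small to turn any called gene, and a minimum mean of 10 removed no tested gene, so neither tests anything. For genes with a mean under 100, the 108 calls of the authors' deposited table compared with 19 by the refit, and the cause was not tested. Leaving out 1 library gave 1 to 145 calls, 1 without A1 or A2, 3 without B2, 14 without A3, 42 without B1 and 145 without B3, and the cause was not tested. Recomputing the adjustment over all genes was not run, since genes without an adjusted p have no p to recover. Other size factors and runs without a library were not run for the whole table, since reads were recovered only below a mean of 100. A camera test was planned for libraries mapped to genotype and was not run on the recovered reads. The recovered tested genes had a median of 280 reads over 6 libraries. On simulated reads with 1 dispersion of 0.03 for all genes, the refit called 68% of genes changed 2-fold and 100% of those changed 4-fold. The dispersion of the real reads was not estimated, so these shares do not give the power of the refit on them.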

Other observations

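Of the tests in this part, those of Gm8420, of Esr1, of the platelet genes and of short RNA recovery were chosen only after the result was seen, while the tests of the small nucleolar RNA host genes and of other splits were written before it. The genes named here were chosen after their values were seen, and log2 values are those of the authors' deposited table.

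Gm8420, a processed pseudogene on chromosome 1 from 51940650 to 51941261, had the largest rise of all called genes at a log2 fold change of 3.15 in the authors' deposited table, with an adjusted p of 4.73e-20. It had 3 recovered reads in group A and 328 in group B, a ratio of 73.5 per summed size factor with an exact 95% interval from 24.9 to 358 that covers counting error only and not the spread between libraries. The ratio of its group means was 84.6, and leaving out 1 library gave 56.4 (without A3) to 134 (without A1). Its transcript is 96.6% identical to that of Rpl15, a ribosomal protein gene, whose value was 0.32 with no adjusted p in the authors' deposited table. Cxcl1, a neutrophil chemokine, was at 65.8 and 59.0 normalized reads in A1 and A2 and at 6.59 in A3, the libraries in which Egr2, Egr3 and Fosb were also unequal.

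Esr1, the oestrogen receptor gene whose ligand-binding part is used in MerCreMer, had a mean of 25169 normalized counts in the authors' deposited table, a level that 60 genes exceeded. If the reads came from the transgene and one group lacked it, that group would hold almost none of them, but the log2 fold change was -0.31 in the authors' deposited table, with a bound on its size of 0.85, which argues against that combination. Transcription of Esr1 from its own locus stays open, since its mean was 5.60 times that of Nr3c1, the highest of 47 other nuclear receptors, and a high level alone does not exclude it. MerCreMer in both groups was not tested and may also give these values, although the labels name it for vTBX5KO alone.

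Among the genes called higher in group B were 14 platelet genes, including F13a1 (0.51), which is also a called marker of the macrophage list. The median log2 fold change of the 14 genes was 1.11 in the authors' deposited table. These platelet genes were picked because they were called, and no list test was run. A single platelet-rich library may contribute, since the summed reads of 10 of them were 1178 in B1, 619 in B2 and 496 in B3 against 188 to 277 in group A, but without B1 the fold was still 2.55. Of 16 further platelet genes listed before their values were seen, 7 were tested, all 7 with a log2 fold change over 0 and 0 called, and the 10 with recovered reads had a fold of 2.47, or 1.67 without B1, with B3 (90.9) below A3 (109), so this stays open. More retained blood stays open too, since red cell genes had a median of 0.48, lower than the called platelet genes by 0.63 but higher than the further tested ones with a median of 0.19. A difference between the genotypes stays open as well and was not tested.

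Of 44 tested genes that GENCODE M21 classes as small nucleolar RNAs, 11 were called higher in group B and 0 lower. Of the 44, 42 had a log2 fold change over 0, and the median was 0.68 in the authors' deposited table. The class includes Mir1949 and Snhg7, both called higher, and Scarna10, whose deposited names point to other kinds of RNA. A matching rise in the RNA of their host genes is argued against, since 31 tested host genes had a median of -0.054 with an interquartile range of 0.26 and 1 call. These reads measure the RNA present and not its transcription, so transcription of the host genes stays open. Better recovery of short RNA in group B may account for the pattern and stays open, since 41 other short RNAs had a median of 0.12 with an interquartile range of 0.66. The 10 snRNAs among them had a median of 0.60. A difference between the genotypes stays open and was not tested, as the letters are not mapped to them.

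The limma-voom refit called 19 genes with the libraries split by letter, and the highest count among the other splits of the 6 libraries was 1, so 1 of 10 splits gave as many. With 10 splits a share under 0.05 is out of reach.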
